A study of Oryza sativa with 28 samples.

How the data were processed

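The arrays measured messenger RNA in leaves of rice seedlings of the cultivar Norin 8, kept in a growth chamber per the labels' protocols and moved from long days (14.5 h of light, 9.5 h of dark) to short days (10 h of light, 14 h of dark). The labels give 28 samples on 3 days: 8 on day 0, the last long day, and 10 each on days 1 and 5 after the shift. Day 0 was sampled at 22:30 and every 2 h from 0:00 to 12:00, and days 1 and 5 every 2 h from 18:00 to 12:00. Seedlings were 14 days old when the series began per the labels' protocols, and 400 ng of RNA was labelled with Cy3 for a 1-colour rice array. A source label speaks of the field while the protocol describes a growth chamber, and the protocol was followed here. Counted from the first sample of each day, the dark ended at 8:00 on all 3 days, an hour that the labels do not print.

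The deposited scanner files hold, per the file headers, 1 fluorescence intensity per spot on a linear scale (the processed signal), which the authors obtained with Agilent Feature Extraction, whose protocol corrected for spatial and multiplicative trends within an array. The file headers name version 10.5.1.1 and the submitters' processing notes version 9.5.3.1, and this difference was not resolved. The series table that the authors deposited holds the same intensity values as the processed signal, spot by spot (largest relative difference 0), so no normalization between arrays had been applied and the table gave no separate alternative. Values in the flag columns (control, outlier, saturation, background) are codes set by the scanner software per the file headers.

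Each array had 45151 spots. After 1417 scanner control spots and 590 custom control spots were left out, 43144 spots of 42418 probes remained, of which 41908 probes carried a locus name of the array design and 510 were named as microRNA. The locus probes stood for 29690 loci, 7801 of them with more than 1 probe. 942 spot values marked as outliers were left out, and no spot was saturated. Spots of a probe were averaged, and a locus with several probes was represented by the probe with the highest mean over the 28 arrays. Each array's median signal lay between 479.7 and 879.6, and between 74.0% and 82.1% of probes were well above background. The lowest median signal was that of day 0 at 12:00, and the lowest share of probes that of day 0 at 10:00. The day 0 arrays from 6:00 to 12:00, all on 1 slide, had 69 to 78 marked spots each, and no other array more than 42. Array quality was thus not separate from day 0 morning. The number of arrays also limits the precision.

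Values were log2 of the processed signal minus the array's 75th percentile. A gene not well above background on any array of a day has only a bound there, taken against each array's lowest signal among probes well above background. Genes well above background on at least 3 of 28 arrays were tested, which gave 24901 genes. limma 3.58.1 in R 4.3.3 (with statmod 1.5.0 and data.table version 1.17.8) fitted clock time (11 levels) and day as factors over all 28 arrays, and eBayes gave 2-sided p-values with Benjamini-Hochberg adjustment at 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the offsets were calculated in R. No clock time of a day had a replicate, so the spread behind each p-value is the variation of day differences over clock times, and nothing in the labels says whether a sample came from 1 plant or a pool.

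The comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a later choice is named as such. The comparisons were day 1 and day 5 against day 0, day 5 against day 1, time of day (an F test), light hours (10:00, 12:00) against dark hours (0:00 to 6:00), the change of this light-minus-dark difference between days (18 arrays), and nights aligned by dusk (15 arrays). The dusk alignment set 22:30 to 6:00 of day 0 against 18:00 to 2:00 of days 1 and 5. After the first step day 0 lay slightly nearer to dusk, so the match is not exact. A descriptive measure asked which alignment of the nights, by dusk or by clock, brought each gene's profiles closer. The named genes were all measured members of the clock and flowering lists, the 8 largest rises and falls per comparison of days and of light with dark with an annotated protein and the same sign at every shared clock time or day, up to 4 members of each other list with the smallest adjusted p, and the 10 widest ranges over clock times. For the largest rises and falls the same sign throughout was a condition of naming and is no separate evidence. The rule gave 165 genes, and the text prints part of them.

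The 31 gene lists covered the circadian clock, photoperiodic flowering, photoreceptors, light-harvesting proteins, the Calvin cycle, chlorophyll synthesis, starch and sucrose metabolism, carbon starvation, nitrogen assimilation, gibberellin, catalases and photorespiration, cell division, age-related SPL genes, leaf senescence, and stress and handling, with root and shoot meristem markers for other tissues. Keyword lists took cytosolic and plastid-type ribosomal proteins, core histones, heat shock proteins, proteasome subunits, cell wall genes, auxin response, ethylene response factors, jasmonate ZIM domain, B-box and CONSTANS-like zinc fingers, glutathione S-transferases, peroxidases, cytochrome P450s and aquaporins from the annotation in the files. Lists were tested with limma's camera at its preset correlation, with the correlation estimated per list as an alternative, and with fry. Members whose annotation contradicted the list were dropped: GID2 and OsbZIP18, 3 potassium channels picked up by the ZIM keyword, and 4 genes picked up by the ethylene keyword. Gene symbols of list members were paired with the loci from general knowledge and held only against the annotation in the files, so some may be wrong, and other genes keep the locus name and annotation of the array design.

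The 28 arrays lay on 7 slides of 4. Day 0 filled slides 1 and 2 and shared none with other days, day 1 lay on slides 3, 4 and part of 5, and day 5 on the rest of slide 5 and slides 6 and 7. Each day spans several slides, so slide was fitted as a random block (duplicateCorrelation, consensus correlation 0.289), and its counts stand beside those of the day comparisons, with its p-values for part of the genes.

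The models were tested on simulated data with 24536 genes and known changes of 100 genes each. Of changes of 1 on the log2 scale, limma recovered 84% for day 1 against day 0, 82% for day 5 against day 0, 83% for day 5 against day 1, 80% for light against dark and 54% for time of day. The share was 9% and 12% for the change of the light-minus-dark difference on days 1 and 5, and 63% and 61% for the dusk-aligned comparisons. In 10 draws with no day effect and a correlation of 0.3 within slides, a mean of 39.7 genes was called for day 1 against day 0, 133.7 for day 5 against day 0 and 36.3 for day 5 against day 1. With no correlation within slides at most 2 were called in any draw. camera and fry each found the 1 shifted list of 10 simulated lists and called no other. Genes of these lists were drawn without correlation between them, while the real cell division list had an estimated correlation of 0.93. The simulation therefore does not show how often correlated lists are called wrongly. The recovered shares above were also simulated with no correlation within slides.

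Alternatives were normexp background correction, quantile and median scaling, no filter or a stricter filter on dim probes, all probes in place of 1 per gene, slide as a fixed or random block, a 2-fold minimum, only the 21 arrays at shared clock times, no clock-time term, 8:00 counted with the light hours, leaving out each clock time and each slide, and other settings of the list tests. Matching day 0 to arrays taken 2 h or 4 h earlier, and the offset in hours of each gene's profile, were chosen after the data were seen. Offsets were searched from -1.5 to 4.5 h in steps of 0.25 h for genes with a range of at least 2 on the log2 scale, a grid that is not centred on 0. No genome was used here, so genes carry locus names and no coordinates.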

Results

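Leaf messenger RNA of rice seedlings (Oryza sativa, cultivar Norin 8) was measured on 28 single-colour arrays through the night and morning of 3 days around a shift from long to short days. Day 0, still on 14.5 h of light, had 8 arrays, and days 1 and 5 on 10 h of light had 10 each. Lights went off 4.5 h earlier after the shift, while the dark ended at 8:00 on all 3 days, both counted from the dark hours and first samples that the labels give. Values are log2 signal relative to each array's 75th percentile, and differences are given with their standard errors from the limma fit. Each clock time of a day had 1 array, so p-values measure how steadily a difference held over clock times, and that spread may be technical. Seedlings were also 1 or 5 days older on days 1 and 5, so age moved with day. The first principal component took 31.2% and the next 18.9% of the variance.

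More genes changed with time of day than between any pair of days. The widest fitted range over clock times, 13.43 on the log2 scale, belonged to the DnaJ-type heat shock gene Os04g0675400, followed by the armadillo-repeat gene Os12g0493900 (12.94). The third was the DnaJ gene Os01g0606900 (11.97). These were well above background on 20, 13 and 8 of 28 arrays, so their low ends are background levels. Among clock genes, OsPCL1, the rice counterpart of the evening complex gene LUX, spanned 10.03, the flavin-binding F-box gene OsFKF1 9.56 (well above background on 19 arrays), OsGI (GIGANTEA) 7.68 and the morning gene OsLHY 6.88. The pseudo-response regulators OsPRR73, OsPRR37, OsPRR95 and OsPRR1 spanned 7.61, 6.77, 6.47 and 5.73, and OsPRR59 2.11. The clock genes OsELF3-1, OsELF3-2 and OsZTL1 had narrower ranges of 1.41, 1.45 and 0.62. Of the 13 clock genes, 12 changed with time of day (13 adjusted over the list alone), with OsZTL2 left out at a range of 0.69 and an adjusted p = 0.0699 by limma with Benjamini-Hochberg adjustment. The same test called 9 of 15 measured flowering genes (9 adjusted over the list alone), 13 of 14 light-harvesting genes (13), 11 of 12 chlorophyll synthesis genes (11), 24 of 26 B-box and CONSTANS-like genes (24) and 17 of 23 starch and sucrose genes (18). limma called 0 of 6 cell division genes (0 adjusted over the list alone, 0 at an unadjusted p under 0.05).

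Over all genes, the limma F test called 13916 of 24897 genes for time of day, against 15554 at an unadjusted p under 0.05, and 13682 with slide as a random block. Of the called genes 9369 spanned at least 2-fold. The count was 9104 without slide 3, 8560 without slide 4, 7766 without slide 7 and 8351 on the 21 arrays at shared clock times.

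**Figure D1:**
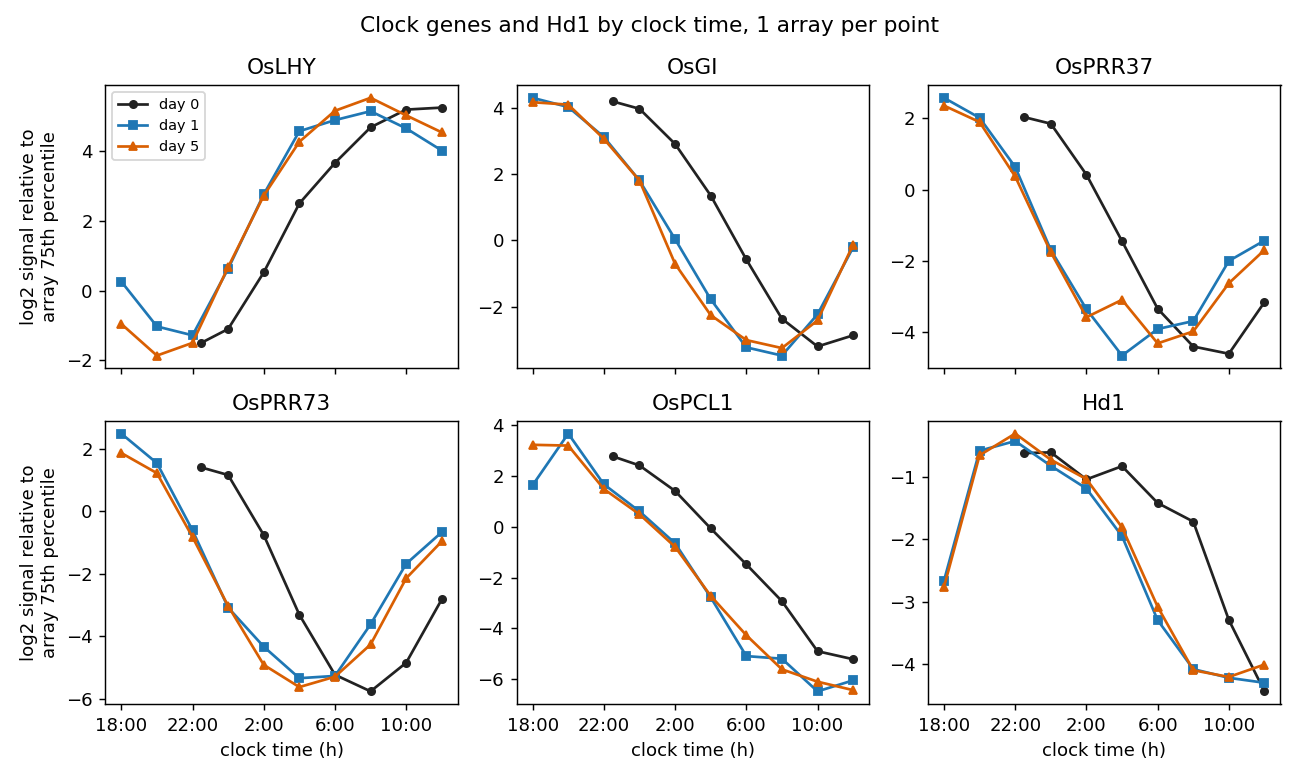
Log2 signal relative to each array's 75th percentile (vertical axes) against clock time in hours (horizontal axes) for OsLHY, OsGI, OsPRR37, OsPRR73, OsPCL1 and Hd1, with 1 line per day and 1 array per point. OsLHY reached its highest value at 12:00 on day 0 (5.26) and at 8:00 on days 1 (5.15) and 5 (5.54).

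Between night and morning, most of the light-harvesting genes measured rose and most of the starch and sucrose genes fell. LHCB_Os03g0592500, a chlorophyll a/b binding protein of photosystem II, rose by 4.01 ± 0.66 on the log2 scale and LHCB3 by 2.44 ± 0.41, each on all 3 days. The blue-light receptor gene CRY2 rose by 2.29 ± 0.18 on 3 of 3 days and OsLHY by 2.18 ± 0.33 on 3 of 3. ASN1, an asparagine synthetase, rose by 4.17 ± 0.26 and PORA, a protochlorophyllide reductase, by 2.25 ± 0.26, both on 3 of 3 days. OsPCL1 fell by 4.78, the thiamine synthesis gene Os03g0679700 (thiC) by 4.80 and the flowering genes Hd1 and DTH2 by 2.61 and 2.56, on every day. The largest of these adjusted p-values was 0.000139 and the smallest 8.91e-10 (limma, Benjamini-Hochberg). The starch debranching gene ISA1 fell by 2.75, and AGPL1, the large subunit of ADP-glucose pyrophosphorylase, by 2.09.

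By list, 12 light-harvesting genes rose and 2 fell of 14 (12 and 2 adjusted over the list alone), and camera placed the list higher (adjusted p = 0.000968, or adjusted p = 0.835 with an estimated correlation). Of 15 photoreceptor and light signalling genes 10 rose and 3 fell (10 and 4 adjusted over the list alone; camera up, adjusted p = 0.0473, or adjusted p = 0.815 with an estimated correlation). Of 23 starch and sucrose genes 0 rose and 15 fell (2 and 15 adjusted over the list alone; camera down, adjusted p = 0.0025, or adjusted p = 0.567 with an estimated correlation). Proteasome subunits had 2 rises and 16 falls of 36 (2 and 19 adjusted over the list alone; camera down, adjusted p = 0.0473, or adjusted p = 0.884 with an estimated correlation). Chlorophyll synthesis had 7 rises and 1 fall of 12 (7 and 1 adjusted over the list alone; not called by camera, adjusted p = 0.0755), the clock 4 and 7 of 13 (5 and 7), and flowering 4 and 6 of 15 (4 and 6). The list test fry called 18 of the 31 lists, where camera called 4. Over all genes limma called 11705 (47.0% of those tested), 5205 up and 6500 down (5834 up and 5623 down with array-median scaling), with 11433 under slide as a random block and 2732 at 2-fold or more. Without slide 7 the count was 7750.

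On day 1 against day 0, at the 7 clock times from 0:00 to 12:00, the evening gene OsPCL1 and starch genes were lower and ASN1 was higher. OsPCL1 fell by 2.17 ± 0.26, lower at each of the 7 clock times (limma, Benjamini-Hochberg adjusted p = 0.000521, or 0.0314 with slide as a random block), and without slide 4 it stood at -1.96 and missed the threshold. Os03g0679700 (thiC) fell by 1.93 ± 0.22 and Os04g0522500, of the isopenicillin N synthase family, by 2.60 ± 0.26, both lower at all 7 times (limma, Benjamini-Hochberg adjusted p = 0.000347 and 0.000166, or 0.015 and 0.00872 with the slide block). These were the only 3 of the 44 named genes called here that the slide block kept. A pair of early light-induced protein genes, Os07g0178800 and Os01g0246400, fell by 2.95 ± 0.54 and 1.77 ± 0.40, and the Myb gene Os06g0205100 by 1.89 ± 0.42, lower at 7, 6 and 7 of 7 times. ASN1 rose by 1.85 ± 0.26 at 7 of 7 times (limma, Benjamini-Hochberg adjusted p = 0.00186). The BURP-domain gene Os10g0409400 rose by 3.14 ± 0.86, the xyloglucan endotransglycosylase gene Os06g0335900 by 2.21 ± 0.50, the photosystem II 10 kDa gene Os07g0147500 by 1.99 ± 0.52 and the rhodanese-like gene Os12g0428000 by 1.89 ± 0.48. The protease inhibitor gene Os03g0823400 rose by 1.60 ± 0.37, and all 5 of these were higher at 7 of 7 times, with limma Benjamini-Hochberg adjusted p from 0.0189 to 0.0425. The same sign at every time was a condition for naming the largest rises and falls, so there it adds nothing to the p-values.

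Of the 13 clock genes OsPCL1 alone passed the test on day 1 (0 up and 1 down over all genes, 1 and 2 adjusted over the list alone). OsLHY stood at 0.99 ± 0.34 and OsGI at -1.20 ± 0.57 (limma, Benjamini-Hochberg adjusted p = 0.0993, higher at 5 of 7 times, and 0.242, higher at 2 of 7). Of 15 flowering genes 2 rose and 2 fell (3 and 2 adjusted over the list alone). Hd1, a CONSTANS-type regulator of heading date, fell by 0.91 ± 0.25, DTH2 fell by 1.04 ± 0.23 and OsCOL4 rose by 0.80 ± 0.22. The other rise was FTL1, which was well above background on 3 of 28 arrays and on none of day 0, so no fold is given. The slide block kept none of Hd1, DTH2 and OsCOL4. Their profiles ran 3.25, 3.5 and 3.5 h late on day 0, so timing and level were not told apart. With day 0 matched 4 h earlier, chosen after the data were seen, OsCOL4 stood at -0.39. Hd1 and DTH2 kept direction in all 31 alternatives and their calls in 10 and 19. The florigen gene Hd3a and its activator Ehd1 were below the detection filter, each well above background on 1 of 28 arrays.

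Starch and sucrose metabolism was lower as a list on day 1 at the same clock times. Of its 23 genes 0 rose and 8 fell (0 and 13 adjusted over the list alone), with a median of -0.51, and camera placed the list lower (adjusted p = 6.9e-07, or adjusted p = 0.0419 with an estimated correlation). DPE2, which handles maltose from starch breakdown, fell by 0.64 ± 0.10 at 7 of 7 times and GWD1, which phosphorylates starch, by 0.33 ± 0.06 at 7 of 7 (limma, Benjamini-Hochberg adjusted p = 0.00272 and 0.00844, or 0.0897 for DPE2 with the slide block). ISA1 fell by 1.04 ± 0.25 and the branching enzyme gene BEIIa by 0.64 ± 0.18, while AGPL1 stood at -1.57 and missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0511, lower at 6 of 7 times). The list test fry called this list and no other on day 1. The profiles of 10 starch genes with wide ranges ran a median of 2.75 h late on day 0. A later profile on day 0 and a lower level on day 1 were therefore not told apart. With day 0 matched 4 h earlier, a choice made after the data were seen, GWD1 stood at 0.089. Of 31 alternatives DPE2 kept its call in 26 and turned in 0, ISA1 kept its call in 18 and BEIIa in 10. Camera also called chlorophyll synthesis up (adjusted p = 0.0289, or adjusted p = 0.978 with an estimated correlation) and the jasmonate ZIM domain list down (adjusted p = 0.0274, or adjusted p = 0.978 with an estimated correlation). In these lists 1 of 12 rose, PORA by 1.16 ± 0.27 (4 adjusted over the list alone), and 1 of 14 fell, JAZ9 by 1.27 ± 0.34 (2 adjusted over the list alone). ZIM genes and light-harvesting genes have close relatives that a probe may not separate. The phytochrome-interacting factor gene OsPIL16 was the 1 photoreceptor list member to rise, by 0.61 ± 0.17 (6 up and 2 down adjusted over the list alone).

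Over all genes, limma called 1311 for day 1 against day 0 (701 up, 610 down; 5283 at an unadjusted p under 0.05), 149 of them at least 2-fold, and 19 with slide as a random block. The count was 588, 644, 356 and 447 without 2:00, 6:00, 8:00 and 10:00, and 3037, 257, 9, 737 and 621 without slides 1, 3, 4, 6 and 7. It was 624 on the 21 arrays at shared clock times and 20 with no term for clock time, and of the 44 named genes called here 10 kept their call without slide 2, 11 without slide 3, 1 without slide 4 and 12 without 8:00.

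**Figure D2:**
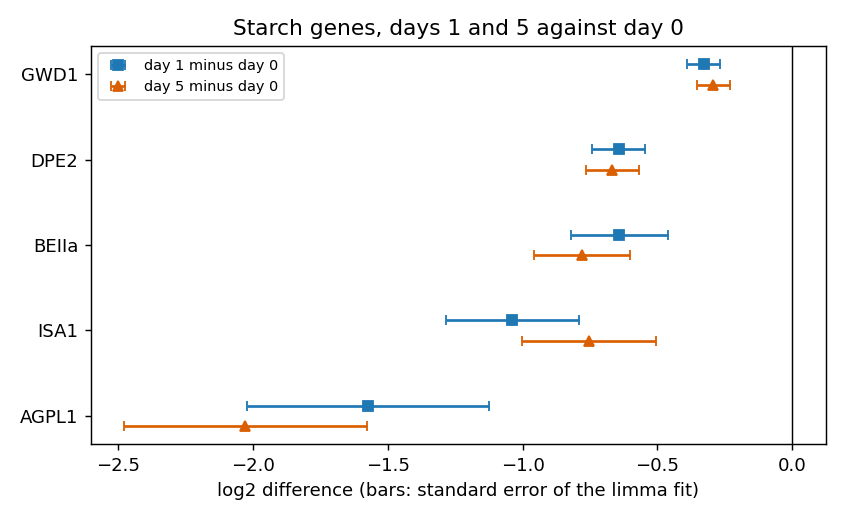
Log2 difference from day 0 (horizontal axis), with standard errors as bars, for AGPL1, ISA1, BEIIa, DPE2 and GWD1 (vertical axis) on days 1 and 5. All values lie below 0, from -0.29 to -2.03, and those of AGPL1 on day 1 and ISA1 on day 5 missed the adjusted threshold.

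On day 5 against day 0 the same directions were seen for OsPCL1, thiC and starch, and a group of genes around nicotianamine synthase rose. OsPCL1 fell by 2.05 ± 0.26 and Os03g0679700 by 1.85 ± 0.22, lower at 7 of 7 times (limma, Benjamini-Hochberg adjusted p = 0.000303 and 0.000183, or 0.0249 and 0.00988 with the slide block). The early light-induced protein gene Os07g0178800 fell by 3.28 ± 0.54 at 7 of 7 times (limma, Benjamini-Hochberg adjusted p = 0.0014, or 0.0579 with the slide block), and without slide 7 it stood at -2.72 and missed the threshold. Os05g0442400, the Myb gene MYBS3, fell by 2.79 ± 0.43 at 7 of 7 times (limma, Benjamini-Hochberg adjusted p = 0.000939, or 0.0481 with the slide block), against -1.08 on day 1, which did not pass. Os06g0335900 rose by 2.67 ± 0.50 and Os12g0428000 by 2.46 ± 0.48, at 7 of 7 times. ASN1 rose by 0.98 ± 0.26 at 6 of 7 times. Of flowering genes 1 rose and 2 fell of 15 (1 and 2 adjusted over the list alone), where Hd1 fell by 0.83 ± 0.25 and DTH2 fell by 0.83 ± 0.23. The rise was FTL1, well above background on 1 array of day 5 and on none of day 0, so no fold is given. Without slide 2 DTH2 stood at 0.0036 and did not pass. Timing and level were not told apart for Hd1 and DTH2 on day 5 either. The clock list had 0 rises and 1 fall (1 and 4 adjusted over the list alone).

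The nicotianamine synthase genes Os03g0307300 and Os03g0307200, whose product chelates iron and other metals, rose by 4.18 ± 0.92 and 3.96 ± 0.90, higher at 7 of 7 times. A rise at all 7 times was a condition of the rule that named them. A further 6 of the largest rises were the ABC transporter gene Os06g0607700 (3.92 ± 0.70), the serine carboxypeptidase gene Os02g0463500 (3.63 ± 0.72), the amino acid transporter gene Os04g0543600 (3.0 ± 0.57), the dioxygenase-family gene Os04g0538900 (2.97 ± 0.61), the prolyl endopeptidase gene Os04g0561500 (2.92 ± 0.65) and Os04g0581100 of the isopenicillin N synthase family (2.82 ± 0.53). Adjusted p for the 8 lay between 0.00243 and 0.0089 (limma, Benjamini-Hochberg), and between 0.066 and 0.137 with slide as a random block, so none of them passed with the block. With normexp correction and quantile scaling the rises of Os06g0607700, Os02g0463500 and Os04g0538900 were smaller, at 1.91, 1.76 and 1.26. These 3 were well above background on 4, 4 and 2 of the 8 arrays of day 0, so their rises start from background levels, while both synthase genes were so on 8 of 8. The group mean was -4.99 ± 1.51 (SD) over the 8 arrays of day 0, -4.62 ± 2.15 over the 10 of day 1 and -2.22 ± 0.67 over the 10 of day 5. The probes of both synthase genes may bind either transcript.

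**Figure D3:**
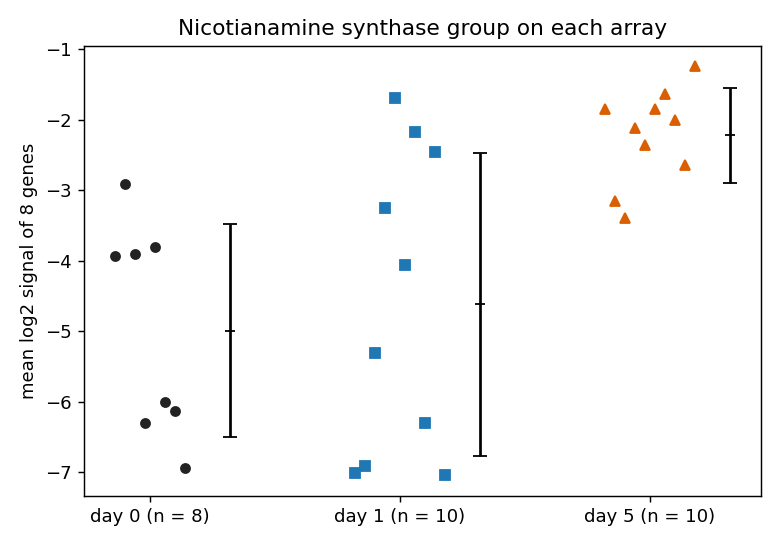
Mean log2 signal relative to each array's 75th percentile (vertical axis) of the 8 genes rising with nicotianamine synthase, 1 point per array by day (horizontal axis), with the mean and SD of each day. Day 5 arrays lie between -3.39 and -1.24, day 0 arrays between -6.94 and -2.90 and day 1 arrays between -7.04 and -1.69.

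Starch and sucrose genes had 0 rises and 11 falls of 23 on day 5 (0 and 13 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 6.1e-06, or adjusted p = 0.0735 with an estimated correlation). AGPL1 fell by 2.03 ± 0.45, DPE2 by 0.67 ± 0.10 and GWD1 by 0.29 ± 0.06, each at 7 of 7 times, and with the slide block DPE2 passed while AGPL1 and GWD1 did not (limma, Benjamini-Hochberg adjusted p = 0.0397, 0.138 and 0.0932). A later profile of starch genes on day 0 was not told apart from a lower level on day 5 either. The jasmonate ZIM domain list had 0 rises and 5 falls of 14 (0 and 5 adjusted over the list alone; camera adjusted p = 0.00583, or adjusted p = 0.937 with an estimated correlation), where JAZ9 fell by 1.33 ± 0.34 and JAZ11 fell by 1.04 ± 0.30. Chlorophyll synthesis had 1 rise of 12, PORA by 0.99 ± 0.27 (1 adjusted over the list alone; camera adjusted p = 0.00583, or adjusted p = 0.937 with an estimated correlation). The list test fry called starch and sucrose metabolism and no other list on day 5. Camera further called plastid-type ribosomal proteins up and proteasome subunits down (adjusted p = 0.016 each, or adjusted p = 0.937 each with an estimated correlation), with 1 rise of 47 (0 adjusted over the list alone), and 1 rise and 3 falls of 36 (1 and 3 adjusted over the list alone). Of 5 age-related SPL genes 2 fell (2 adjusted over the list alone), OsSPL13 by 0.62 ± 0.14 and OsSPL12 by 0.36 ± 0.08.

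Over all genes, limma called 3298 for day 5 against day 0 (1673 up, 1625 down; 7125 at an unadjusted p under 0.05), 453 of them at least 2-fold, and 234 with slide as a random block, which kept 7 of the 60 named genes called here. Of the day 5 changes printed above, those of OsPCL1, Os03g0679700, Os05g0442400 and DPE2 were kept, and the others were not. The split by direction depended on processing, with 1881 up and 1236 down under array-median scaling and 1701 up and 2634 down without the filter. The count was 1976 and 1649 without 6:00 and 8:00, 2095, 1859 and 117 without slides 3, 4 and 7, and 365 with no term for clock time, and of the 60 named genes 21 kept their call without slide 2 and 4 without slide 7.

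Both comparisons use the same day 0 arrays. Their log2 differences had a correlation of 0.787 across genes, which are not independent replicates, where simulated unchanged days gave 0.623, and a covariance of 0.102 where these gave 0.0351. The sign was the same for 79.6% of genes (71.4% simulated). Of called genes 570 were higher in both and 518 lower in both, where independent lists would share 47.1 and 39.8, a figure that leaves out the shared day 0 arrays, which raise the overlap, and 0 were called in opposite directions. With the day 0 arrays split between the comparisons the correlation was 0.413 or 0.603. The simulated days had no correlation within slides, and each part of the split still drew on both slides of day 0. A slide effect common to the day 0 arrays could therefore raise the observed values without any effect of the day.

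Between day 5 and day 1, at 10 shared clock times, limma called 0 genes, with 2598 at an unadjusted p under 0.05 where 1245.1 would come by chance, and 0 with slide as a random or fixed block. The nicotianamine synthase genes stood 2.97 ± 0.80 and 3.25 higher on day 5, at 8 of 10 times each, and did not pass (limma, Benjamini-Hochberg adjusted p = 0.194 and 0.151). Os05g0442400 stood at -1.71 ± 0.37 and ASN1 at -0.87 (limma, Benjamini-Hochberg adjusted p = 0.125, higher at 1 of 10 times, and 0.186, higher at 2 of 10). Camera placed plastid-type ribosomal proteins higher on day 5 (adjusted p = 1.5e-08, or adjusted p = 0.588 with an estimated correlation), and cytosolic ribosomal proteins (adjusted p = 0.000381) and the Calvin cycle (adjusted p = 0.0128) higher, with core histones (adjusted p = 0.0128) and SPL genes (adjusted p = 0.038) lower. For these last 4 the adjusted p = 0.952 with an estimated correlation, and no member of the 5 lists passed over all genes (1 plastid ribosomal rise and 2 SPL falls adjusted over the list alone). The list test fry passed none of the 31 lists here (smallest Benjamini-Hochberg adjusted p = 0.198, for plastid-type ribosomal proteins, with limma). Leaving out 0:00 gave 63 genes, leaving out 10:00 gave 1, leaving out slide 6 gave 13, and quantile scaling gave 1.

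The step from night to morning differed between day 0 and the later days for many genes, several clock genes among them. On day 1 the light-minus-dark difference was greater than on day 0 by 5.13 for OsPRR73, 4.93 for OsPRR37, 4.51 for OsGI, 3.14 for OsFKF1 and 2.38 for OsPRR1, and smaller for OsLHY (-2.71), PORA (-1.87) and the chloroplast fructose-bisphosphatase gene cpFBPase (-1.96). On day 5 the values were 4.96, 4.27, 4.72, 2.48 and 1.77, and -2.25, -1.46 and -2.21. The isocitrate lyase gene Os07g0529000 changed by 10.11 on day 1 and 9.88 on day 5, and by 7.05 and 6.31 with normexp correction and quantile scaling. It was well above background on 4, 4 and 5 arrays of days 0, 1 and 5, so its low ends are background levels, and it reached 2.10 and 2.15 at 12:00 on days 1 and 5 and at most -4.01 on day 0. The Myb gene Os07g0443500 went the other way (-5.02 and -5.40). These all passed limma's test, with Benjamini-Hochberg adjusted p from 0.000264 to 0.0113. Each day had 2 light and 4 dark arrays, so the direction was not counted by clock time. The light arrays of day 0 at 12:00 and 10:00 had the lowest median signal and the lowest share of probes well above background, respectively. limma called 8614 genes (34.6% of those tested) on day 1 (5046 greater, 3568 smaller; 11326 at an unadjusted p under 0.05) and 5452 (21.9%) on day 5 (2867 and 2585; 9095 unadjusted), with 7172 and 4912 under the slide block. With quantile scaling the split turned, to 4014 and 4341 on day 1 and 2275 and 2723 on day 5, and likewise with normexp correction (4048 and 4200, 2365 and 2700). On day 5 it also turned without 2:00, 4:00, 6:00, 10:00 or 12:00. Without 10:00 or 12:00 the counts were 4595 and 4077 on day 1 and 2999 and 752 on day 5, and without 2:00 or 4:00 they were 3059 and 3206 on day 5. With 8:00 as a light hour they were 3418 and 2068. The split turned here too, to 1665 greater and 1753 smaller on day 1 and 952 and 1116 on day 5.

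With nights aligned by dusk, OsPCL1 and thiC did not pass the test while AGPL1 and a pair of early light-induced protein genes fell. OsPCL1 stood at 0.38 on day 1 and 0.51 on day 5 (limma, Benjamini-Hochberg adjusted p = 0.42 and 0.268), and Os03g0679700 at 0.26 and 0.51. OsGI stood at 0.29 and 0.11 and OsPRR37 at 0.13 and -0.05, while OsFKF1 rose by 1.28, OsPRR1 by 0.70 and OsPRR73 by 0.55 on day 1 (limma, Benjamini-Hochberg adjusted p from 0.0379 to 0.0422). AGPL1 fell by 3.25 ± 0.46 on day 1 and 3.29 ± 0.46 on day 5, and BEIIa by 0.70 and 0.69. Os07g0178800 fell by 3.09 and 2.80 and Os01g0246400 by 2.61 and 2.77. ASN1 rose by 1.86 ± 0.37 on day 1 and stood at 0.66 on day 5, where it did not pass. The photosystem II gene Os07g0147500 rose by 2.24 and 2.05, and the protease inhibitor gene Os03g0823400 by 1.44 and 1.37. OsCOL4 fell on day 5 by 1.04, and the flowering repressor gene DTH8 rose by 0.52 and 0.47. limma called 2095 genes on day 1 (1217 up, 878 down) and 3029 on day 5 (1791 up, 1238 down), with 1650 and 2690 under the slide block, and leaving out 1 of the 5 steps gave 444 to 931 and 357 to 1854. Among these 15 arrays no slide held more than 1 day. The slide block (consensus correlation 0.0205 here) could therefore not part slide from day, and slide effects are not excluded. Aligned by the clock, with partly other arrays of days 1 and 5, the comparison gave 1267 on day 1 and 2944 on day 5.

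The profiles of 46.2% of 24756 genes on day 1 and of 60.5% of 24776 genes on day 5 lay closer to day 0 when aligned by dusk than by the clock. Among genes called for time of day the shares were 49.2% and 59.4%.

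The hours by which day 0 profiles ran late were estimated per gene, a measure chosen after the data were seen and limited to between -1.5 and 4.5 h. The median was 3 h against day 1 over 3663 genes (quartiles 1.25 and 3.5) and 2.75 h against day 5 over 3672 genes, where day 5 against day 1 gave 0.25 h over 3684 genes. OsGI ran 3.5 and 3.75 h late on day 0, OsPRR37 3.75 h against both days, OsPCL1 3.25 h, and OsLHY 2.5 and 2.25 h. The medians of 11 light-harvesting genes were 3 and 3.5 h, those of 10 starch genes 2.75 and 2.875 h, and those of 4 stress genes 1.75 and 1.625 h. OsGI was lowest at 10:00 on day 0 (-3.20) and at 8:00 on days 1 and 5 (-3.47 and -3.25), and Hd1 peaked at 0:00 on day 0 (-0.60) and at 22:00 on days 1 and 5 (-0.41 and -0.29). With day 0 matched to arrays taken 4 h earlier, also chosen after the data were seen, OsPCL1 stood at 0.25 on day 1 and 0.36 on day 5 and Os03g0679700 at 0.27 and 0.35, and none of these passed limma's test.

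**Figure D4:**
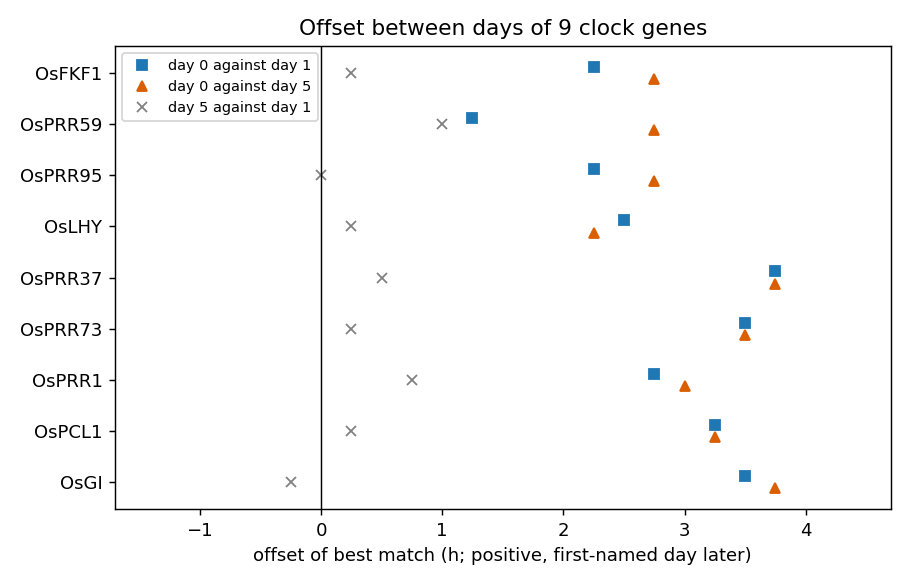
Offset in hours (horizontal axis) of the profiles of 9 clock genes (vertical axis) for day 0 against day 1, day 0 against day 5 and day 5 against day 1, where a positive value means a later profile on the first-named day. The day 0 offsets lie between 1.25 and 3.75 h.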

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

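The tests of a recording offset, of the offset by the later dusk, of root markers and of OsNAAT1 below were chosen after the results were seen, and the test with slide means removed was added once the test of steps within slides had left its question open.

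For 27 of the 76 genes checked, the difference between morning light and night was unlike that of day 0 on day 1, and for 21 on day 5, each by limma's interaction test with Benjamini-Hochberg adjusted p under the threshold. Over all genes the same test called 34.6% on day 1 and 21.9% on day 5, so such changes were not particular to these genes. In the clock, the change on day 1 and then day 5 was 5.13 and 4.96 for OsPRR73, 4.93 and 4.27 for OsPRR37, 4.51 and 4.72 for OsGI, 3.14 and 2.48 for OsFKF1, 2.38 and 1.77 for OsPRR1, 1.63 and 2.27 for OsPRR95, and -2.71 and -2.25 for OsLHY. OsPCL1 changed by 1.34 on day 1 and OsELF3-2 by 1.44 on day 5. Among flowering genes OsCOL4 changed by -1.42 and OsMADS14 by 0.82 on day 1, OsMADS15 by -0.96 and -1.14 and OsMADS50 by -0.67 on both days. In carbon metabolism and photosynthesis, AGPL1 changed by 2.20 and BEIIa by 1.16 on day 1, ISA1 by -1.47 and -1.55, cpFBPase by -1.96 and -2.21, CatA by 2.00 and 2.04, PORA by -1.87 and -1.46, and CHLH by -1.83 on day 1. The isocitrate lyase gene Os07g0529000, at background levels on most arrays, changed by 10.11 and 9.88, and CRY2 by 1.06 on day 5. Among regulators, the Myb genes Os07g0443500, Os04g0583900 and Os06g0205100 changed by -5.02 and -5.40, -3.79 and -3.39, and -2.93 and -3.04. JAZ11 and the ZIM gene Os09g0439200 changed by 2.09 and 1.51 on day 1, and OsSPL12 by -0.50 on day 5. Os05g0500000 changed by -2.27 and -2.10, and Os04g0522500 by -1.87 on day 1.

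A first pattern is that profiles on day 0 ran later than on days 1 and 5, by a median of 3 h against day 1. A slide effect added to the day 0 arrays is argued against by the offsets with slide means removed, a median of 3 h against both days where days 1 and 5 parted the same way gave 0.25 and -0.25 h, although the steps within slides, planned first, leaned towards such an effect without deciding it (mean difference of correlations -0.098, SD 0.267 over 3 step pairs). Clock times recorded with a constant error on day 0 stay open, since the day 0 offsets of 9 clock genes, each averaged over the comparisons with days 1 and 5, spread over 1.75 h (single offsets from 1.25 to 3.75 h), and those of day 5 against day 1 over 1.25 h (from -0.25 to 1 h). The later dusk on day 0 stays open too, since the median of 3 h is the pattern itself, and profiles aligned by dusk were closer for 46.2% of genes on day 1 and 60.5% on day 5 (49.2% and 59.4% of time-of-day genes). Seedling age and other effects of the day, and slide effects that are not additive, stay open and were not tested, and day 0 shares no slide with the other days.

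A second pattern is the rise of the 8 genes with both nicotianamine synthase genes on day 5, by a mean of 3.43 over day 0. Root tissue in the day 5 samples is argued against by the root markers fixed for that purpose, whose mean difference was -0.045 (Lsi1 -0.33 ± 0.27, RCc3 0.24 ± 0.50). A change in iron state of the plants stays open, since the correlations of 6 other iron uptake genes with the group over the 28 arrays went both ways, from -0.58 (OsIRT1) to 0.773 (OsDMAS1), so that their median of -0.059, between OsIRO3 and OsIRO2, and the bound set for it beforehand decide nothing, and the list had left out OsNAAT1 (0.877), while 2 ferritin genes, which iron state would move the other way, had a median of -0.025. A slide effect may contribute and cannot be told apart, since on the slide that held both days the day 5 arrays lay 2.24 above the day 1 arrays with a standard error of 2.39, an error brought in after that value was seen. On that slide the day 5 arrays were of 18:00 and 20:00 and the day 1 arrays of 10:00 and 12:00, so clock time differed too. A biological effect of the day or of age on these genes stays open and was not tested.

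Dixon's test picked 3 arrays in 237 groups of values, each group the values of 1 day over its clock times. For replicates the test marks about 1 in 20 groups by chance, which would be 11.85 here. Clock times are not replicates and the genes share arrays, so that rate does not hold and the picks are descriptive. Os07g0178800 stood at -5.33 at 12:00 on day 5, with the nearest other array at -1.99. OsPRR95, a gene that changed widely with clock time, stood at 1.05 at 22:30 on day 0, the only array of that day before midnight, with the nearest other array at -1.63. The array of 10:00 on day 0 had 74.0% of probes well above background, with the next lowest of that day at 77.6%.

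Chance in the assignment of arrays to groups was examined by exchanging arrays, on 24536 genes measured on every array. For day 1 against day 0 chance could not be excluded, with 1316 genes for the real assignment and up to 5506 for others, and 4 of 64 assignments gave as many. The 5506 came from exchanging 10:00 and 12:00, the 2 light hours. This exchange moves the change of the light-minus-dark difference, called for 8614 genes on day 1, onto the day difference. The day 1 arrays of these hours also share slide 5, and a slide effect was not told apart from it. With the slide block the real assignment gave 19 genes. For day 5 against day 0 chance was excluded (1 of 64, real 3286, highest other 1139), but the exchanges break up slides, day 0 fills slides of its own, and the count was 234 with the slide block and 117 without slide 7, so slide effects are not excluded. Chance was also excluded for time of day (1 of 100 drawn, 13800 and 2818), light against dark (1 of 100 drawn, 11598 and 5600) and the light-minus-dark change on day 1 (1 of 32, 8596 and 6943) and day 5 (1 of 32, 5462 and 3709). For the first 2 of these the highest other count varies with the assignments drawn. Exchanges for these comparisons also break up slides. The light hours lay on slides 2, 5 and 7 and most dark hours on slides 1, 3, 4 and 6, so slide effects are not excluded here either. For day 5 against day 1 the real assignment gave 0 genes, so each of the 100 drawn (highest other 0) had to give as many, and nothing about chance follows from it. The dusk-aligned comparisons have too few assignments for such a test (1 of 16 each, with 2092 real and 4 highest other on day 1, and 3060 and 1 on day 5).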

How the results depend on the processing

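Matching day 0 to arrays taken 2 h or 4 h earlier was chosen after the results were seen, and the other alternatives were planned. Of 211 alternative values of the counts and shares, 152 stayed within 1.5 times the reported one or within its spread, and 59 did not. For the shares of profiles closer by dusk, that spread was a binomial interval over genes. Genes are not independent replicates, so the interval is likely too narrow and small shifts fell outside it. For the named genes, 6861 of 8288 alternative values kept direction and side of the threshold, 1405 kept direction only and 22 turned. Both totals include the series table, which holds the same values, and fits without 22:30, which cannot move the day or light comparisons. Part of the values that stayed was therefore fixed in advance. The labels give no replicate numbers, and the reported fit pairs the days by clock time, so the fit with no clock-time term is its unpaired alternative. In each case below the cause was not tested, except where fewer arrays, a stricter rule or more probes are part of the alternative itself.

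With slide as a random block the count was 19 for day 1 and 234 for day 5 against day 0. Testing all probes gave 2141 and 4960, a 2-fold minimum gave 149 and 453, and 2732 for light against dark, and no clock-time term gave 20 and 365. The 21 arrays at shared clock times gave 624 for day 1 and 8351 for time of day. Quantile scaling gave 1 gene for day 5 against day 1. Counting 8:00 with the light gave 3418 and 2068 for the light-minus-dark change on days 1 and 5, and aligning by clock gave 1267 in place of 2095 for the dusk-aligned day 1. An estimated correlation left 1 of 17 list calls. The share of profiles closer when aligned by dusk was 58.6% on day 5 with normexp, 42.5% on day 1 and 62.1% on day 5 without the filter, 59.2% on day 5 without the first step, and 49.2% and 59.4% among time-of-day genes.

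Leaving out 1 clock time gave 356 (without 8:00) to 1873 genes for day 1 and 1649 (without 8:00) to 3528 for day 5 against day 0, 0 to 63 (without 0:00) for day 5 against day 1, 12298 to 14222 for time of day and 8702 to 11887 for light against dark. Leaving out 1 slide gave 9 (slide 4) to 3037 (slide 1), 117 (slide 7) to 4028, 0 to 13 (slide 6), 7766 (slide 7) to 16362 and 7750 (slide 7) to 12363. The light-minus-dark change ranged over 4077 (without 12:00) to 9515 on day 1 and 752 (without 12:00) to 6463 on day 5, and the dusk-aligned counts over 444 to 931 and 357 to 1854, lower at each of the 5 steps left out.

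Values turned sign as follows, with none past the adjusted threshold after turning. With day 0 matched 4 h earlier, the day 1 and day 5 differences were 0.25 and 0.36 for OsPCL1, 0.27 and 0.35 for Os03g0679700, 0.089 and 0.13 for GWD1, 0.59 and 0.68 for Os04g0675400, 0.14 and 0.50 for Os05g0500000, 0.27 and 0.77 for Os06g0581500, 0.16 and 0.33 for Os07g0677400, and 0.24 and 0.40 for Os10g0389500. So matched, ASN1 was -0.17 on day 5 and OsCOL4 -0.39 on day 1. Matched 2 h earlier, Os06g0581500 was 0.19 on day 5 and OsCOL4 -0.023 on day 1, while OsPCL1 was -0.84 and -0.73. DTH2 ranged from -1.45 (without slide 1) to 0.0036 (without slide 2) on day 5, and Os04g0522500 was 0.033 for the light-minus-dark change on day 1 with normexp. Signal over background limits Hd3a and Ehd1, and the series table gave no alternative because it holds the same values.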

Other observations

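The hours by which profiles differ, the similarity of arrays across days and the genes rising with nicotianamine synthase were looked at after the data were seen, while the gene lists were planned.

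For light against dark, limma's camera called none of the following lists, with Benjamini-Hochberg adjusted p from 0.0755 to 0.966, while fry, which does not compare a list with other genes, called gibberellin (adjusted p = 0.000102), ethylene response factors (0.00254), SPL genes (0.00275), auxin response (0.00328) and ZIM genes (0.00656) among others. The gibberellin 20-oxidase genes SD1 and GA20ox1 rose by 2.14 ± 0.24 and 1.55 ± 0.19 in the light on 3 of 3 days (limma, Benjamini-Hochberg adjusted p = 3.02e-06 and 5.57e-06), the 2 rises of 7 gibberellin genes (2 adjusted over the list alone). The cold-response regulator DREB1A rose by 3.49 ± 0.64 on 3 of 3 days and the senescence-list gene Osh36 by 1.59 ± 0.17 on 3 of 3. The aquaporin genes Os02g0658100 and Os09g0541000 fell by 2.05 and 1.80 on all 3 days, in a list with 6 rises and 5 falls of 16 (6 and 5 adjusted over the list alone). Over all genes limma called 47.0% for light against dark, so list counts near that share show nothing particular to a list. Auxin response had 17 rises and 8 falls of 54 (17 and 8 adjusted over the list alone), ethylene response factors 19 and 8 of 51 (19 and 8) and heat shock proteins 35 and 18 of 104 (35 and 18). Cytochrome P450s had 34 and 65 of 201 (35 and 67), cell wall genes 8 and 17 of 59 (7 and 17), glutathione S-transferases 10 and 15 of 52 (10 and 15), peroxidases 27 and 25 of 114 (27 and 25), and B-box and CONSTANS-like genes 12 and 6 of 26 (12 and 6). The Calvin cycle had 1 and 3 of 12 (0 and 2), nitrogen assimilation 1 and 3 of 7 (1 and 3), carbon starvation 1 and 1 of 4 (1 and 1), catalases and photorespiration 2 and 1 of 5 (2 and 1), and senescence 2 and 0 of 5 (2 and 0). Stress and handling had 1 and 2 of 11 (1 and 2), core histones 1 and 6 of 46 (1 and 3), cytosolic ribosomal proteins 1 and 7 of 148 (1 and 3) and plastid-type ribosomal proteins 1 and 7 of 47 (1 and 1). SPL genes had 0 and 3 of 5 (0 and 4) and ZIM genes 1 and 6 of 14 (1 and 6).

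On day 5 against day 0 limma called 13.2% of all genes. Cytochrome P450s had 11 rises and 20 falls (12 and 24 adjusted over the list alone), peroxidases 7 and 13 (7 and 13), heat shock proteins 7 and 8 (7 and 10), glutathione S-transferases 2 and 6 (2 and 8), auxin response 5 and 0 (4 and 0) and B-box and CONSTANS-like genes 4 and 4 (7 and 4). Ethylene response factors had 4 and 3 (4 and 3), cell wall genes 4 and 4 (4 and 4), aquaporins 2 and 2 (3 and 2), nitrogen assimilation 0 and 2 (1 and 2), stress and handling 0 and 2 (1 and 4) and carbon starvation 1 and 0 (1 and 0). Of 14 light-harvesting genes limma called 0 (2 at an unadjusted p under 0.05), of 46 histones 0 (4) and of 5 senescence genes 0 (1). Of 7 gibberellin genes limma called 0 (3 unadjusted, and 1 rise and 1 fall adjusted over the list alone). It called 0 with 0 at an unadjusted p under 0.05 for the Calvin cycle, for catalases and photorespiration, for cell division, and for root and shoot meristem markers with 2 measured members each. Cell division genes also gave 0 for light against dark and for day 1, with 0 unadjusted in both.

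Each of the 8 arrays of day 0 was most like an array of day 1 taken 2 to 4.5 h earlier by the clock, and the same held against day 5, over 3651 genes with wide ranges. The day 0 array of 0:00 had a correlation across these genes of 0.671 with 20:00 of day 1 and of 0.279 with 0:00 of day 1. With day 0 matched 2 h earlier limma called 935 genes on day 1 and 2979 on day 5, and with 4 h 1155 and 3779.

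The 8 genes that rose with nicotianamine synthase on day 5 also varied together within the days, with a median correlation between members of 0.891 over the 28 arrays after clock time and day were removed, a description without a test because the genes were picked for their rise. OsDMAS1, a deoxymugineic acid synthase gene, rose by 1.18 on day 5 (limma, Benjamini-Hochberg adjusted p = 0.0108), and OsYSL2, well above background on 8 of 28 arrays, by 1.08 (0.0303). OsIRO2 (1.43), OsIRO3 (0.36), OsIRT1 (-0.19), OsYSL15 (-0.43) and the ferritin genes OsFER1 (0.042) and OsFER2 (-0.0057) did not pass.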
